A study of Homo sapiens with 6 samples.

How the data were processed

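RNA was sequenced from 6 GST pulldowns out of HEK 293 lysate, 3 with GST alone as bait and 3 with the GST-Ferry complex as bait. Per the labels' protocols, the bait proteins were bound to glutathione resin, the washed resin was incubated with fresh lysate and washed again, and the recovered RNA was depleted of ribosomal RNA and made into strand-specific libraries. The authors deposited one table of raw read counts per gene, with 60676 Ensembl gene IDs in rows and the 6 libraries in columns. Per the submitters' processing notes, bcl2fastq 2.19.1, STAR 2.5.2b and the GRCh38.p13 build were used. The counting program, the annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here, so counts of near-identical copies, of overlapping genes and of antisense genes are uncertain. Per the file headers, the columns are named as control or sample with a replicate number. Control was taken as GST and sample as GST-Ferry, number for number, from the words alone, and this reading is an assumption about which library is which.

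Gene symbols, types and coordinates came from GENCODE release 29 and a table of gene names, which gave a symbol for 58575 of the IDs and a gene type for 58503. Library totals ran from 2454538 to 10466520 counts, and a floor of 3 counts corresponded to between 0.287 CPM in GST 2 and 1.22 CPM in GST-Ferry 3, which covers counting error only. Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15546 genes, holding 99.5% to 99.7% of each library's counts. Libraries were scaled with TMM factors (0.923 to 1.1), and normalised read counts are CPM computed from the deposited counts. Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with no covariate and Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p under 0.05 are called enriched (higher with GST-Ferry) or depleted (lower with GST-Ferry). Fold changes are log2 of GST-Ferry over GST, and SE is the standard error from the fit. No library of RNA from the input lysate was analysed here, so every value is a comparison between the baits, relative to the total of each library.

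A set of 26 gene lists was fixed before the data were examined, and 24 of them had at least 5 tested members. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 24 lists. Camera with a correlation estimated from the libraries and fry, which tests whether the genes of a list move one way on balance, were run beside it. Genes are named by a rule fixed before the data were examined. It takes enriched and depleted genes with a mean of at least 10 CPM and no overlap between the groups, namely the 12 protein-coding genes with the largest fold change and the 8 with the smallest, and 4 genes of other types at each end. It adds the 3 genes with the highest mean CPM, all bait subunits, and up to 3 called members of each list in each direction or, where none was called, its most abundant member. Genes named outside this rule are marked as chosen after their values were seen.

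The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries of the same bait differed by far more than counting noise (chi-square per degree of freedom from 4.43 to 50.3), so none was counted as a duplicate. The procedure was tested on simulated counts for the 15546 genes. It recovered 4 of 67 genes changed by 1.5-fold, 32 of 69 changed by 2-fold and 47 of 64 changed by 3-fold, and 3.49% of its calls were false. The simulated counts were drawn independently for each gene. They held no correlation between genes and no differences between libraries that many genes share. The recovery and the share of false calls may therefore not hold for the real libraries. Alternatives listed before the data were examined were another scaling (RLE size factors, library sizes alone), the filter on low counts, a threshold of 0.01, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of small and mitochondrially encoded RNAs, and each library left out in turn. Chosen after seeing the data were library weights, leaving out GST 3 and GST-Ferry 1 together, thinning to equal depth, offsets for GC content and transcript length, and removal of the 5 bait subunit genes. Figures were drawn with matplotlib 3.10.9.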

Results

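RNA that bound to the FERRY complex was compared with RNA that bound to the affinity tag alone. FERRY is an effector of the early endosomal GTPase RAB5 and consists of the 5 subunits TBCK, PPP1R21, C12orf4, CRYZL1 and GATD1. The complex fused to GST (GST-Ferry), or GST by itself as the control for nonspecific binding, was incubated with lysate of HEK 293 cells, an established human embryonic kidney line grown here in suspension. Each bait gave 3 libraries. The GST libraries held 9388865, 10466520 and 7390346 counts, and the GST-Ferry libraries held 6532665, 2671831 and 2454538 counts. Between 25441 and 27177 genes were detected in the GST libraries, against 25610, 20883 and 20705 in the GST-Ferry libraries. Protein-coding genes took 89.6% ± 2.25 of counts with GST and 93.3% ± 1.39 with GST-Ferry (mean ± SD, n = 3 each). The first principal component, with 42.9% of the variance, had all GST libraries below 0 and all GST-Ferry libraries above 0. GST 3 lay at -56.4 on it, far from GST 1 at -13.2, and GST-Ferry 1 lay nearest to the GST libraries at 4.43.

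The mRNAs of 3 of the 5 subunits of the bait itself were by far the most enriched RNAs on GST-Ferry. PPP1R21 rose 454-fold, from 41.6 ± 2.73 CPM with GST to 18900 ± 18400 CPM with GST-Ferry (mean ± SD, n = 3 each). C12orf4, also known as FERRY3, rose 106-fold from 60.7 ± 9.88 to 6440 ± 5650 CPM, and TBCK, which has a TBC domain of the kind found in RAB GTPase-activating proteins, rose 39.5-fold from 99.4 ± 21.9 to 3931 ± 3270 CPM. The other 2 subunit mRNAs did not pass the test: GATD1 had 124 ± 31.2 CPM with GST and 135 ± 25.8 CPM with GST-Ferry, and CRYZL1 had 88.6 ± 13.8 and 63.3 ± 14.8 CPM.

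The log2 fold changes of the 3 raised subunit mRNAs were 8.83 ± 1.08 (SE) for PPP1R21, 6.73 ± 0.77 for C12orf4 and 5.31 ± 0.68 for TBCK, each with an adjusted p of 0.0111 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same test GATD1 had a log2 fold change of 0.12 ± 0.23 (adjusted p = 0.808) and CRYZL1 of -0.50 ± 0.22 (adjusted p = 0.248). The level differed widely between the GST-Ferry libraries. Without GST-Ferry 2 none of the 3 raised subunit mRNAs passed edgeR's quasi-likelihood test (adjusted p = 0.0633 for PPP1R21 and C12orf4, 0.0769 for TBCK). Over the refits that tested them, the lowest log2 fold change was 7.65 for PPP1R21, 5.88 for C12orf4 and 4.53 for TBCK. PPP1R21 had 797.9 CPM in GST-Ferry 1, 18290 CPM in GST-Ferry 2 and 37620 CPM in GST-Ferry 3, against 39.4 to 44.6 CPM in the GST libraries. The 5 subunit genes together took 0.249%, 2.72% and 5.35% of the counts of GST-Ferry 1, 2 and 3, and 0.0423% ± 0.00736 with GST. PPP1R21 lies on chromosome 2 (48440598 to 48515391, plus strand), C12orf4 on chromosome 12 (4487728 to 4538508, minus strand) and TBCK on chromosome 4 (106041599 to 106321495, minus strand) of GRCh38, as GENCODE 29 places them. As a list, the FERRY subunits were higher with GST-Ferry by camera (Benjamini-Hochberg adjusted p = 6.8e-07; adjusted p = 0.27 with an estimated correlation).

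**Figure D1:**
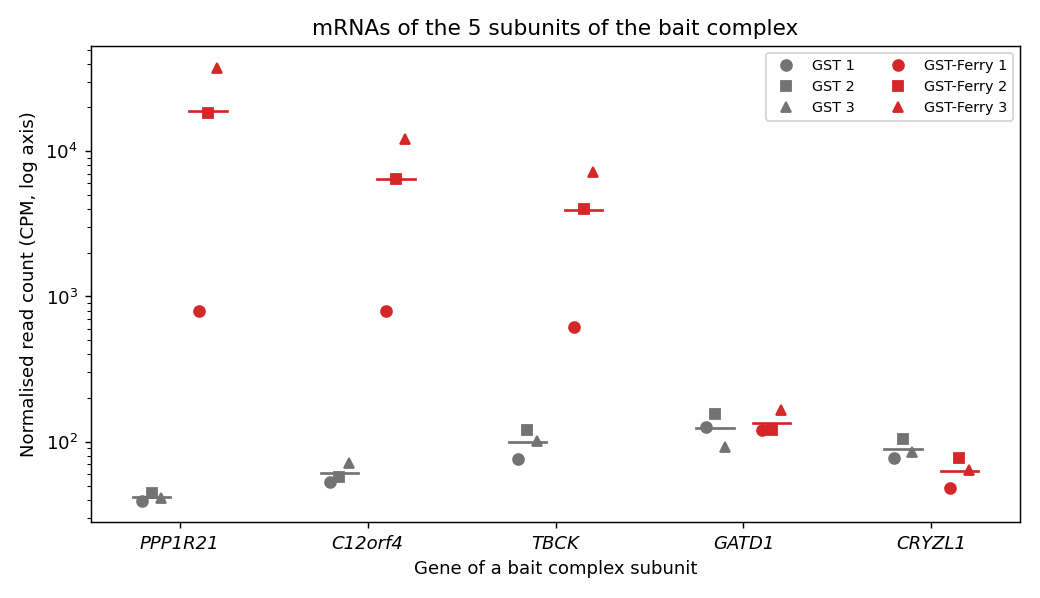
Normalised read counts (CPM, log axis) of the mRNAs of the 5 FERRY subunits in each library; grey is GST, red is GST-Ferry, symbols give the replicate number and lines give the mean of each group. PPP1R21, C12orf4 and TBCK lie above all GST libraries in each GST-Ferry library, with GST-Ferry 1 lowest, while GATD1 and CRYZL1 stay near their GST level.

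Beyond the bait subunits, GST-Ferry enriched a modest set of mRNAs by about 2 to 4-fold, among them GSTP1, PRDX1 and VPS8 and mRNAs of histones and mitochondrial proteins. The glutathione S-transferase GSTP1 rose from 183 ± 5.69 to 582 ± 146 CPM, a log2 fold change of 1.67 ± 0.22 (SE). The peroxiredoxins PRDX1 and PRDX2, which reduce peroxides, rose by 1.66 ± 0.21 and 1.42 ± 0.22 on the log2 scale, PRDX1 from 206 ± 24 to 652 ± 116 CPM. Among called genes, the largest change outside the bait was in TICAM1, an adaptor of Toll-like receptor signalling, with a log2 fold change of 2.06 ± 0.38 from a low level of 6.39 ± 0.62 CPM. VPS8, a subunit of the CORVET complex that tethers early endosomes, rose from 135 ± 26.1 to 377 ± 139 CPM (log2 fold change 1.49 ± 0.27).

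In all, 92 of 15546 tested genes were enriched and 5 were depleted by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 87 of the enriched genes were at 2-fold or more. The enriched genes were protein-coding in 91 cases, and the median rise outside the bait subunits was 2.27-fold. The remaining genes named by size of change were BEGAIN (log2 fold change 1.70 ± 0.29), the dioxygenase ALKBH4 (1.50 ± 0.28), the flap endonuclease FEN1 (1.45 ± 0.19), the outer mitochondrial membrane protein TSPO (1.45 ± 0.22) and the glutathione peroxidase GPX1 (1.05 ± 0.20), which GENCODE 29 does not type as protein-coding. Adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0111 for PRDX1, 0.0123 for GSTP1 and FEN1, and between 0.0397 and 0.045 for the other genes named here outside the bait. All 92 enriched and all 5 depleted genes had groups that did not overlap, against 27.1% of all tested genes and 10% by chance.

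The 5 depleted genes were the lysophosphatidic acid receptor LPAR6, the microRNA host gene MIR222HG, the divergent transcript ZMPSTE24-DT, the nuclear transport receptor RANBP17 and the tetratricopeptide repeat gene TTC14. LPAR6 had 15.9 ± 4.27 CPM with GST and 4.39 ± 0.763 CPM with GST-Ferry (log2 fold change -1.80 ± 0.32), and its span lies within that of RB1 on the opposite strand. MIR222HG had a log2 fold change of -1.35 ± 0.26, ZMPSTE24-DT of -1.27 ± 0.26, RANBP17 of -0.99 ± 0.20 and TTC14 of -0.90 ± 0.18, with adjusted p-values from 0.042 to 0.048 over the 5 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TTC14 was tight within both groups, with 133 ± 3.89 CPM against 71 ± 5.08 CPM. The calls lay close to the threshold, with 65 further genes at adjusted p-values from 0.05 to 0.06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the scaling and single libraries changed which were called. All 5 depleted genes kept a fold change below 0 in every refit, which their groups without overlap largely settled beforehand. All 5 calls were lost with RLE size factors (adjusted p = 0.0518 to 0.0558 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with library sizes alone (0.0626 to 0.0741), with limma-voom (0.0641 to 0.0741), and without GST 2, GST-Ferry 1, GST-Ferry 2 or GST-Ferry 3. With offsets for GC content and transcript length MIR222HG, ZMPSTE24-DT and TTC14 were lost, and TTC14 was also lost without GST 1 and ZMPSTE24-DT at equal depth. Without GST-Ferry 2 the test called 0 genes (910 higher and 794 lower at an unadjusted p under 0.05), without GST-Ferry 3 or without GST 2 it called only the 3 bait subunits, without GST 3 it called 701 enriched and 558 depleted genes, without GST 1 it called 19 depleted genes and without GST-Ferry 1 it called 3 others.

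**Figure D2:**
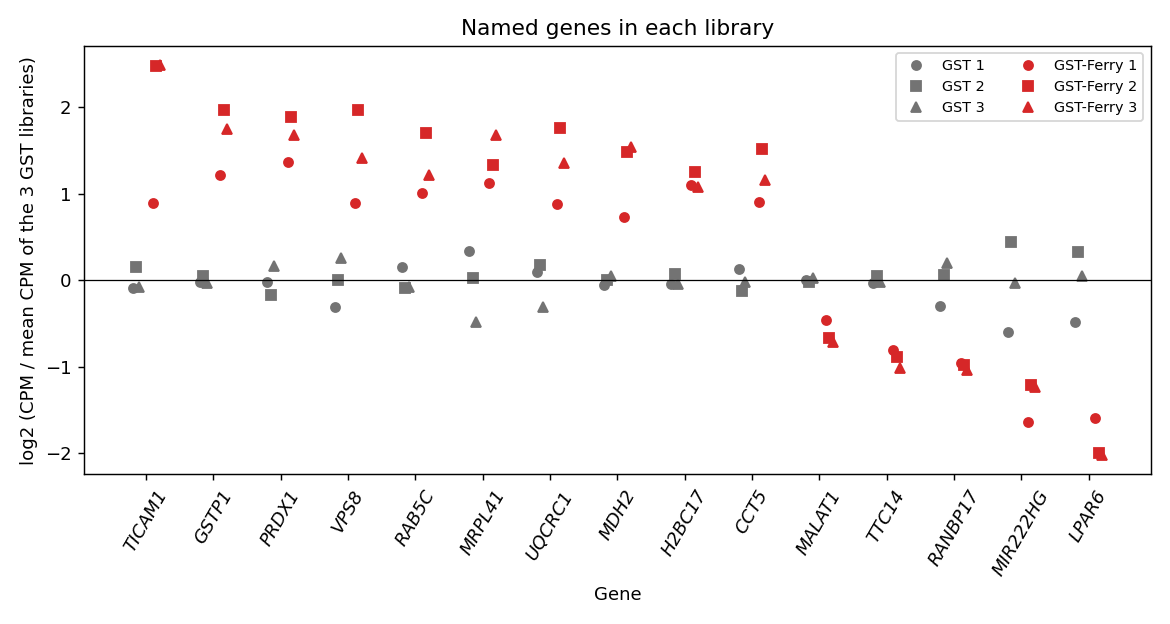
Level of 15 named genes in each library, as log2 of CPM over the mean CPM of the GST libraries; grey is GST, red is GST-Ferry and symbols give the replicate number. The GST-Ferry libraries lie above all GST libraries from TICAM1 to CCT5 and below them from MALAT1 to LPAR6; MALAT1 did not pass the test.

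Nuclear-encoded mRNAs for mitochondrial proteins were higher as groups with GST-Ferry by camera with a preset correlation, though not with an estimated one (adjusted p = 0.27 to 0.32). Of 80 tested subunits of oxidative phosphorylation, 76 had a fold change above 0 and 5 were enriched, with a median log2 fold change of 0.49. Among them UQCRC1 of complex III rose from 88.5 ± 15.2 to 230 ± 69 CPM (log2 fold change 1.37 ± 0.24), COX6B1 of cytochrome c oxidase rose by 1.18 ± 0.22 and ATP5F1B, the catalytic beta subunit of ATP synthase, rose by 1.15 ± 0.22. Relative to the GST mean, the mean log2 CPM of the oxidative phosphorylation list was -0.27, 0.04 and 0.23 in GST 1, 2 and 3. In GST-Ferry 1, 2 and 3 it was 0.26, 0.64 and 0.61, so GST-Ferry 1 lay close to GST 3. All 18 enzymes of the TCA cycle and pyruvate dehydrogenase list had a fold change above 0, with a median of 0.49, and malate dehydrogenase MDH2 rose from 158 ± 5.69 to 388 ± 108 CPM. Of 81 mitochondrial ribosomal protein mRNAs, 64 had a fold change above 0 and 2 were enriched, MRPL41 (log2 fold change 1.38 ± 0.25) and MRPL12 (1.14 ± 0.22).

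By camera with Benjamini-Hochberg adjustment, adjusted p was 1.9e-15 for the oxidative phosphorylation list, 4.5e-07 for the TCA cycle list, 2.2e-09 for mitochondrial ribosomal proteins (median log2 fold change 0.36) and 0.00023 for mitochondrial import and chaperones (median 0.38, 0 of 37 members enriched). With an estimated correlation none of these lists passed (adjusted p = 0.27, 0.27, 0.32 and 0.27). Over all 24 tested lists, 13 were higher and 3 lower by camera and 0 passed with an estimated correlation, and a split of the 6 libraries that exchanged GST 3 and GST-Ferry 1 between the groups shifted 20 lists. The 6 single genes named here as risen had adjusted p-values between 0.042 and 0.045 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 27 oxidative phosphorylation genes were enriched and 1 was depleted, and 9 TCA cycle genes, 17 mitochondrial ribosomal protein genes and 12 import genes were enriched. HSPD1, the most abundant import and chaperone mRNA, had 688 ± 29.6 CPM with GST and 973 ± 189 CPM with GST-Ferry and did not pass the test. The 13 mRNAs of the mitochondrial genome had a median log2 fold change of -0.01 (camera, adjusted p = 0.71), which passed as higher without GST-Ferry 2 (median 0.24, adjusted p = 0.02) and as lower without GST 3 and GST-Ferry 1 (median -0.28, adjusted p = 0.022). The difference between these mRNAs and the nuclear-encoded ones was not tested. MT-CO1 had 2806 ± 257 CPM with GST and 2791 ± 503 CPM with GST-Ferry.

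Histone mRNAs were the list with the highest median outside the bait subunits, except without GST-Ferry 1, where glycolytic enzymes had a median log2 fold change of 0.93 and histones of 0.92. Of 43 replication-dependent histone mRNAs, which lack a poly(A) tail, 41 had a fold change above 0 and 13 were enriched, with a median log2 fold change of 0.88. H2BC17 rose from 71 ± 3.34 to 157 ± 10.2 CPM, H2BC18 from 91.5 ± 7.72 to 201 ± 20.5 CPM and H2AC4 from 18.8 ± 2.46 to 45.4 ± 6.67 CPM. This rise was even across the GST-Ferry libraries, where the mean log2 CPM of the list lay 0.70, 0.85 and 0.89 above the GST mean. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 5.2e-30, and adjusted p = 0.061 with an estimated correlation; adjusted over the list alone, 36 members were enriched. Histone genes share near-identical coding sequences, so the split of reads between single members is uncertain.

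Housekeeping enzymes and folding machines followed at smaller size. Glycolytic enzymes had a median log2 fold change of 0.80 with all 17 members above 0 and triosephosphate isomerase TPI1 enriched (225 ± 21.4 to 488 ± 111 CPM). Proteasome subunits had a median of 0.54, and the catalytic subunit PSMB6 was the 1 of 33 that was enriched (log2 fold change 1.18 ± 0.23). Chaperonin and cytosolic chaperone mRNAs had a median of 0.36 with 22 of 24 above 0, and CCT5 of the TRiC chaperonin rose from 423 ± 38.9 to 982 ± 214 CPM. Immediate-early and other short-lived mRNAs had a median of 0.44 with 0 of 25 enriched, and TXNIP, the most abundant, had a log2 fold change of -0.16 ± 0.45. Spliceosome proteins had a median of 0.33, and SF3B5 rose by 0.94 ± 0.19. Camera with Benjamini-Hochberg adjustment gave adjusted p = 5.8e-12 for glycolysis, 1.7e-09 for the proteasome, 3.5e-05 for chaperones, 9.6e-05 for short-lived mRNAs and 0.00038 for spliceosome proteins. None passed with an estimated correlation (adjusted p = 0.27 for the first 4 lists and 0.35 for spliceosome proteins). Adjusted over the list alone, 12 glycolytic, 14 proteasome, 4 chaperone, 1 short-lived and 5 spliceosome mRNAs were enriched, and 1 chaperone mRNA was depleted.

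Among lists around the endosomal system to which FERRY belongs, early endosome genes and microtubule motors lay slightly higher by camera with a preset correlation. Neither passed with an estimated correlation, and lysosome genes did not pass as a list. Of 28 early endosome and RAB5 genes, 17 had a fold change above 0 and 2 were enriched: VPS8 and the RAB5 isoform RAB5C, which rose from 13.1 ± 1.3 to 33.1 ± 8.5 CPM (log2 fold change 1.32 ± 0.24). The list's median log2 fold change was 0.16 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.017; adjusted p = 0.35 with an estimated correlation), and the call was lost without GST 1 (adjusted p = 0.051) and without GST-Ferry 2 (adjusted p = 0.07). Microtubule motors of the dynein, dynactin and kinesin list had a median of 0.14 with 21 of 27 members above 0 and 0 enriched (camera, adjusted p = 0.02; adjusted p = 0.27 with an estimated correlation), a call lost without GST 2 (adjusted p = 0.082), without GST-Ferry 2 (adjusted p = 0.051) and at equal depth (adjusted p = 0.079). The dynein heavy chain DYNC1H1 had 1132 ± 174 and 1193 ± 57.8 CPM. Lysosome and V-ATPase genes did not pass as a list (median 0.16, camera adjusted p = 0.091) but did without GST 3 (adjusted p = 0.026) and without GST-Ferry 1 (adjusted p = 0.03), and the V-ATPase subunits ATP6V0D1 (log2 fold change 1.36 ± 0.24) and ATP6V0E2 (1.04 ± 0.20) were enriched. Adjusted over the list alone, 5 early endosome, 0 motor and 3 lysosome genes were enriched.

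snoRNA host genes, nuclear-retained lncRNAs and spliceosomal snRNAs lay lower with GST-Ferry as groups by camera with a preset correlation, with no single member past the test over all genes. Of 25 snoRNA host genes, 24 had a fold change below 0, with a median of -0.74, and SNHG29, the most abundant, had 683 ± 268 CPM with GST and 446 ± 29.7 CPM with GST-Ferry. Nuclear-retained lncRNAs had a median of -0.35; MALAT1 had 10840 ± 154 CPM with GST and 7112 ± 672 CPM with GST-Ferry (log2 fold change -0.61 ± 0.23). Together this list took 1.35% ± 0.089 of counts with GST and 0.912% ± 0.161 with GST-Ferry. The mean log2 CPM of its members, relative to the GST mean, overlapped between the groups. It was -0.12 in GST-Ferry 1 and -0.18 in GST 1, with GST-Ferry 2 and 3 at -0.63 and -0.41. Spliceosomal snRNAs had a median of -1.75, which was set largely by GST 3: RNU4-2 had 414.7 CPM there against 9.82 and 36.7 CPM in GST 1 and GST 2 and 39.8 ± 20.1 CPM with GST-Ferry, and the median was -0.66 without GST 3. The groups overlapped for the snRNA list too, with its mean log2 CPM at -1.295 in GST 1 and -0.89 in GST-Ferry 3, relative to the GST mean. The snRNA call was lost without GST 3 and GST-Ferry 1 together (median -0.39, adjusted p = 0.44) and with library weights (median -0.35, adjusted p = 0.14). Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.7e-09 for snoRNA host genes, 0.0019 for nuclear lncRNAs and 9.6e-05 for snRNAs (adjusted p = 0.27, 0.35 and 0.27 with an estimated correlation). Adjusted over the list alone, 11 snoRNA host genes, 2 nuclear lncRNAs and 8 snRNAs were depleted.

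The mRNAs of the cytosolic translation machinery and of the secretory pathway did not pass as lists. For several of the lists below, the libraries included or the processing decided the call. Cytosolic ribosomal proteins, at 5.01% ± 0.896 of counts with GST and 4.45% ± 0.573 with GST-Ferry, had a median log2 fold change of -0.17 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.058), which was 0.02 without GST 3, and RPS4X had 2656 ± 1030 and 2280 ± 346 CPM. Without GST 1, GST-Ferry 2 or GST-Ferry 3 this list passed as lower (camera, adjusted p = 4.5e-07, 0.00032 and 0.023), and without GST 3 and GST-Ferry 1 together it passed as higher (median 0.19, adjusted p = 0.022). It was called in 10 of 19 settings, among them DESeq2, library sizes alone and no filter on low counts, each with all 6 libraries. Translation factors had a median of 0.01 (camera, adjusted p = 0.1), with EEF2 at 2507 ± 295 and 3713 ± 570 CPM, and passed as higher without GST 3 (median 0.11, adjusted p = 0.019) and without GST-Ferry 1 (median 0.10, adjusted p = 0.0049). They also passed as higher with library weights, with GC and length offsets and with no filter on low counts, where the median was -0.05. Without GST 3 and GST-Ferry 1 together they passed as higher too (median 0.21, camera, adjusted p = 0.00024). ER translocation and folding genes had a median of 0.02 and a mean of -0.004 (adjusted p = 0.87), with CANX at 760 ± 150 and 617 ± 27.6 CPM. Zinc-finger genes (415 tested) had a median of -0.11 (adjusted p = 0.1), with ZNF207 at -0.62 ± 0.27, and passed as lower without GST-Ferry 1 (median -0.16, adjusted p = 0.03). snoRNAs and scaRNAs had a median of -0.35 (adjusted p = 0.15), with SNORD3A at 0.52 ± 0.37; they passed as lower without GST 1 (median -0.71, adjusted p = 0.0049), while the median was 0.09 without GST 3. Markers of other lineages, of which only 6 were abundant enough to test, had a median of 0.12 (adjusted p = 0.92), with COL1A1 at 33.8 ± 14.6 and 53.6 ± 3.38 CPM. Adjusted over the list alone, 6 translation factors, 2 ER genes and 1 snoRNA were enriched, 1 lineage marker was depleted, and no member of the ribosomal protein, zinc-finger or mitochondrial genome lists was called.

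The most abundant RNAs apart from PPP1R21 were XIST and the signal recognition particle RNA RN7SL1, and neither passed the test. XIST had 43670 ± 9480 CPM with GST and 27180 ± 3630 CPM with GST-Ferry (log2 fold change -0.68 ± 0.28). RN7SL1 had 35150 CPM in GST 3 against 1695 and 3806 CPM in GST 1 and GST 2, and 6017 ± 2100 CPM with GST-Ferry. Small noncoding RNAs accordingly took 3.67% of the counts of GST 3 and at most 1.0% of those of the other libraries. The mitochondrial rRNA and tRNA list and the list of cytoplasmic small noncoding RNAs each had only 2 tested members and were not tested as lists; MT-RNR2 had 189 ± 90.7 and 337 ± 398 CPM.

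**Figure D3:**
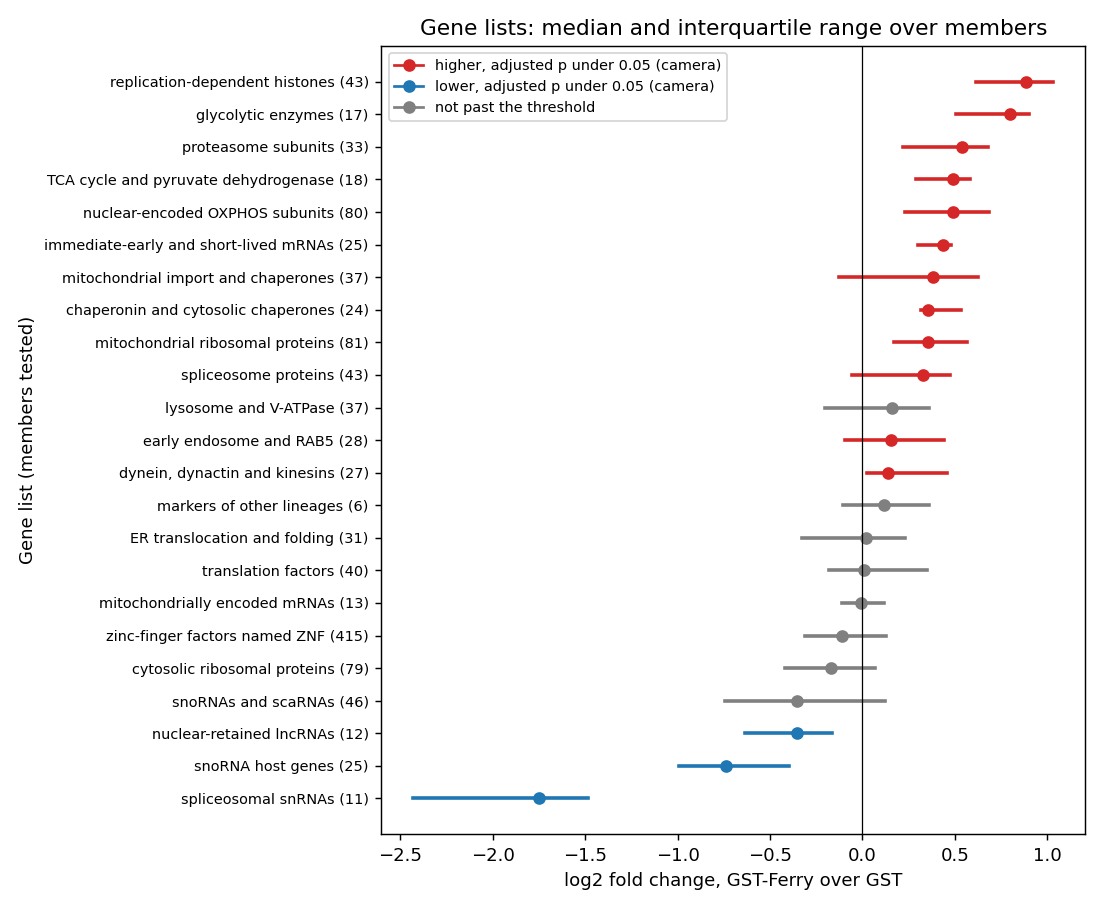
Median (points) and interquartile range (lines) of the log2 fold change of GST-Ferry over GST over the tested members of each gene list, without the FERRY subunits; red and blue mark lists higher and lower by camera with a preset correlation. Histones (0.88) and glycolytic enzymes (0.80) have the highest medians and spliceosomal snRNAs (-1.75) the lowest; none of the lists passed with an estimated correlation.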

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

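All 92 enriched genes kept a fold change above 0 in each of the 19 refits that tested them. Their groups did not overlap, so the kept sign was largely settled by the selection. How many passed the threshold depended on the setting, and the cause was not tested except where the setting itself shows it. At an adjusted p under 0.01, 0 genes were enriched and 0 depleted by edgeR, against 1755 higher and 1251 lower at an unadjusted p under 0.05. RLE size factors gave 11 enriched genes (11 enriched genes at 2-fold or more) and 0 depleted genes, library sizes alone gave 7 (7) and 0, and limma-voom gave 14 (14) and 0. With no filter on low counts 421 genes were enriched (135 at 2-fold or more) and 323 depleted among 32648 tested, and DESeq2 gave 534 (164) and 177. Replicate numbers did not pair the libraries (correlations of deviations 0.25, 0.079 and -0.13, and only replicate 1 correlated best with its own number); with the replicate block 167 genes were enriched (152 at 2-fold or more) and 28 depleted, TTC14 not among them. Without small and mitochondrially encoded RNAs 9 genes were depleted. Leaving out 1 library gave 0 to 701 enriched genes, 0 to 127 at 2-fold or more, 0 to 558 depleted genes and 15 to 19 shifted lists; the lowest counts of enriched genes came without GST-Ferry 2, the highest without GST 3. The settings in this and the next sentence were chosen after seeing the data: library weights in limma-voom gave 1621 enriched (233 at 2-fold or more) and 927 depleted genes, and leaving out GST 3 and GST-Ferry 1 together gave 1754 (341) and 992. Thinning to equal depth gave 11 depleted genes, and GC and length offsets gave 246 enriched and 40 depleted genes, with 73 of the 92 among them. The sign of the log2 fold change differed from that of the main fit in 27 comparisons of single genes, over 8 genes: 2 passed the threshold, RN7SL1 (log2 fold change 0.88) and RNU4-2 (1.085) without GST 3 and GST-Ferry 1, both abundant in GST 3, and the others passed in neither fit. These others were MT-RNR2 (-0.56), RPS4X (0.23), DYNC1H1 (-0.027) and TXNIP (0.46) without the same 2 libraries, RN7SL1 (0.75), RPS4X (0.125), TXNIP (0.39) and RNU4-2 (0.92) with library weights, GATD1 (-0.086), MT-CO1 (0.082) and TXNIP (0.034) with offsets, DYNC1H1 (-0.003) with library sizes alone, RN7SL1 (0.14) with the block, and some without 1 library, where the log2 fold change ran from -1.71 to 1.11 for RN7SL1, -2.56 to 0.68 for RNU4-2, -0.82 to 1.235 for MT-RNR2, -0.46 to 0.10 for RPS4X, -0.58 to 0.205 for TXNIP, -0.084 to 0.29 for GATD1, -0.12 to 0.088 for MT-CO1 and -0.041 to 0.19 for DYNC1H1. The 16 shifted lists became 0 with an estimated correlation and 5 by fry (histones, glycolytic enzymes, chaperonin and cytosolic chaperones, microtubule motors and short-lived mRNAs), and 15 to 20 in the other settings. Of the comparisons of single genes across settings, 736 kept their direction and side of the threshold, 200 kept the direction and fell short of it, and 15 kept the direction and passed it newly. The lowest library total, 2454538 counts in GST-Ferry 3, limits what can be seen of rare RNAs, and the simulated recovery of 5.97% at 1.5-fold limits what can be said of small changes.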

Other observations

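The peroxiredoxins, 12 other redox enzymes and the subunits of endosomal tethers were looked at as families chosen after their values were seen, and were not tested as lists. Of the 6 peroxiredoxins, PRDX5 was enriched (log2 fold change 1.30 ± 0.21, SE) beside PRDX1 and PRDX2, while PRDX6 (0.78 ± 0.22), PRDX3 (0.37 ± 0.36) and PRDX4 (0.21 ± 0.20) did not pass the test. Of the 12 other redox enzymes 4 were enriched, GSTP1, GPX1, biliverdin reductase BLVRB (1.25 ± 0.25) and carbonyl reductase CBR1 (1.23 ± 0.24). The 8 not called were NQO1 (0.94 ± 0.39), superoxide dismutase SOD1 (0.83 ± 0.21), GPX4 (0.66 ± 0.20), TXN (0.51 ± 0.29), catalase CAT (0.39 ± 0.23), GSR (0.38 ± 0.22), TXNRD1 (0.36 ± 0.20) and SOD2 (0.12 ± 0.24). Among subunits of the endosomal tethers CORVET and HOPS, VPS8 alone was enriched; VPS18 had a log2 fold change of 0.99 ± 0.27, VPS11 of 0.81 ± 0.26, VPS16 of 0.62 ± 0.26, TGFBRAP1 of 0.46 ± 0.22, VPS33A of 0.40 ± 0.29, VPS39 of 0.26 ± 0.19 and VPS41 of 0.05 ± 0.19.

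By gene type, also examined only after the data were seen, the 12864 protein-coding genes had a median log2 fold change of 0.02, while 549 lincRNAs and 681 antisense transcripts both had a median of -0.36. Without GST 3 and GST-Ferry 1 these medians were 0.03, -0.61 and -0.65. Camera with Benjamini-Hochberg adjustment over 8 gene types gave adjusted p = 1.1e-08 for protein-coding genes (0.0063 with an estimated correlation), 5e-09 for lincRNAs (0.33) and 2.7e-08 for antisense transcripts (0.38). Enriched mRNAs were short: 88 enriched protein-coding genes outside the bait had a median coding length of 699 nt, against 1442 nt for the other protein-coding genes. None of 10000 random sets matched on mean CPM had a median as short, the lowest being 1160 nt. Split by coding length into 4 bins of nearly equal size, the bin of shortest genes (75 to 897 nt) held 54 enriched genes and that of the longest (2292 nt or more) held 2. Their transcripts also had a median GC content of 58.4% against 48.8%. Across genes, which are not independent replicates, the log2 fold change correlated with GC content (Spearman 0.59), and 0.27 without GST 3 and GST-Ferry 1; the deviation of GST 3 from the gene means correlated with GC content at -0.82, and that of the other libraries between 0.044 and 0.6. The correlation of the log2 fold change with coding length was -0.19, and -0.24 after offsets for GC content and transcript length. With mRNA length, the deviation from the gene means correlated at 0.22, -0.033 and 0.25 in GST 1, 2 and 3. In GST-Ferry 1, 2 and 3 this correlation was 0.011, -0.28 and -0.26, so GST-Ferry 1 lay near GST 2.

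Of the tests in the paragraphs that follow, those on other splits of the libraries were planned before the data were seen; the tests on depth, GC content, coding length, nuclear RNA, the bait subunits and GST-Ferry 1 were chosen only after the result was seen. The mRNAs of PPP1R21, C12orf4 and TBCK differed from other raised mRNAs in how their excess was spread over the libraries: GST-Ferry 1 showed 2.71%, 7.98% and 9.42% of the excess over GST seen in GST-Ferry 2 and 3, whereas 311 other genes at 2-fold or more there showed a median of 44.8% with a 5th percentile of 18.2%. The ratio of the excess in GST-Ferry 2 to that in GST-Ferry 3 was 0.486, 0.531 and 0.556, against a median of 1.11 and a 5th percentile of 0.615 over the same genes. Only 9 of the 311 other genes had as low a ratio, and 2.25% showed as low a share of the excess in GST-Ferry 1. The 3 genes thus lay at the low edge of the others. Capture from the lysate in the same way as other raised mRNAs stays open all the same, since the comparison rests on single libraries. Nucleic acid carried in with the bait preparation stays open too. The excess of C12orf4 and TBCK kept its ratio within 1.2-fold over the GST-Ferry libraries. Ratios to PPP1R21 changed by 3.03-fold and 3.64-fold, and GATD1 and CRYZL1 did not rise. Carried-in nucleic acid need not keep one ratio between genes or cover all 5 subunits, so these values cannot decide on it. Specific binding of FERRY to these 3 mRNAs, the biological explanation the design gives, is also open, as untested.

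The 456 tested members of the 12 raised lists other than the bait subunits had a median log2 fold change of 0.43, and 84.4% lay above 0. Both values reflect that these lists were picked as higher in the same libraries. At equal depth the median was 0.959 of its value. Thinning keeps each gene's expected share of the counts, so it cannot decide on depth beyond counting noise and the filter. With offsets that brought the correlation with GC content to 0.062 the median was 0.988 of its value. This argues against GC content for the pooled median only. The members' median GC content was 49.7%, near the 48.9% of all protein-coding genes tested. Single lists moved both ways with the offsets. The median fell from 0.44 to 0.26 for short-lived mRNAs and rose from 0.36 to 0.52 for chaperone mRNAs. The offsets left the trend on coding length. Other mRNAs matched on coding length had a median log2 fold change of 0.07, which is 0.165 of that of the list members. The lists were pooled because they were raised, and the matched mRNAs came from the remaining genes. A lower median of the matched mRNAs was therefore favoured by the selection, and coding length stays open. More nuclear RNA in the GST libraries stays open. Nuclear-retained lncRNAs had a median log2 fold change of -0.35, though the list means of the groups overlapped. XIST took 4.40% ± 0.536 of counts with GST and 2.66% ± 0.535 with GST-Ferry. Of the 17 nuclear-encoded mRNA lists 15 had a median above 0, with ribosomal proteins and zinc-finger genes below it. Preferential binding of these mRNAs to FERRY is one hypothesis that stays open, and may be weighed against other differences between the baits, such as in the amount of bait protein, on which no value was analysed here.

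GST-Ferry 1 lay between the GST libraries and GST-Ferry 2 and 3 for most raised mRNAs. A GST library carrying the wrong label is argued against by the 3 raised bait subunits, each at least 5.13-fold above the highest GST library there. A constant share of GST-like background RNA in that library could lower all raised mRNAs alike and stays open. The share of the excess seen in GST-Ferry 1 was taken over genes at 1.5-fold or more in the mean of GST-Ferry 2 and 3. This choice favours a low share in GST-Ferry 1. Over 1510 such genes outside the bait and histones, GST-Ferry 1 showed a median of 44.6% of the excess (quartiles 28.6% and 62.6%). Over 35 histone mRNAs the median was 67.4% (quartiles 44.2% and 84.5%), so that the ranges overlapped. Medians of the other raised lists ran from 7.91% over 6 short-lived mRNAs to 49.7% over 5 mRNAs of microtubule motors, with 27.4% over 12 spliceosome mRNAs. The 3 raised bait subunits showed 2.71% to 9.42%. Over all 25 short-lived mRNAs tested, the mean log2 CPM lay 0.25, 0.42 and 0.53 above the GST mean in GST-Ferry 1, 2 and 3. A share that differs between lists is not excluded by these values. What else set GST-Ferry 1 apart was not tested, and no biological explanation was tested.

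The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 92 enriched genes, 87 at 2-fold or more and 5 depleted genes, and the highest of the other splits gave 0 for each, so that 1 split in each case, the real one, gave as many. Every other split put both baits in each group, so a difference between the baits widens the spread within its groups. Few calls in those splits were therefore favoured beforehand. For gene lists the real split shifted 16 and the highest other split shifted 20, and 4 of the 10 splits shifted as many as the real one. The split with 20 set GST 1, GST 2 and GST-Ferry 1 against the rest, which points to a structure among the libraries beside the bait.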
